A study of Mus musculus with 4 samples.

How the data were processed

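Cortical RNA was measured on 4 dual-colour Agilent mouse arrays. Per the labels' protocols, total RNA (200 ng) came from the cerebral cortex of male mice aged 3 months, was extracted with RNeasy and was amplified and dyed with Cy3 or Cy5. Per the labels, each array paired 1 wild-type sample (Cy3) with 1 sample labelled Ndrg2 knockout (Cy5), numbered as replicates 1 to 4, and no array had the dyes exchanged. Genotype and dye therefore could not be separated. The file headers place all 4 arrays on 1 slide in 1 scan, so there was no batch to compare.

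The authors extracted the images with Agilent Feature Extraction; the version is 11.0.1.1 per the file headers and 10.7.3.1 per the submitters' processing notes. Per the file headers, the raw intensity of a spot is its median pixel signal in each channel, with the local background given separately. Per the file headers, the processed signal is that intensity after background subtraction and dye normalization within the array, and a log10 ratio of red over green processed signal is given for each spot. The authors also deposited log2 values in a table, with 1 value per probe and array. Per its own values, the deposited log2 ratio was that of red over green processed signal, so that positive values are higher in the samples labelled knockout. It was not centred further, as its column medians were 0.04, 0.03, -0.04 and -0.04.

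Ratios were computed again from the raw intensity, with R 4.3.3, limma 3.58.1 and data.table (version 1.17.8). The mean pixel signal planned at first was not used here, as the columns analysed here give the median pixel signal, which was used instead. Local background was removed with limma's normexp method and an offset of 50, and each array was normalized by loess with its 1377 control spots at weight 0. Among 43020 other spots per array, 802 outlier spots over the 4 arrays, as marked by Feature Extraction, were left out, and none was saturated. The 399 probes printed as replicate spots were averaged. Of 39429 probes, 27664 were kept because they were well above background on all 4 arrays in at least 1 channel.

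Gene symbols came from matching the transcript accession of each probe to a reference gene table of assembly GRCm38.p6. Symbols were found for 27427 probes (20832 genes), among them 27410 of 27938 probes with RefSeq transcript accessions, and 12002 probes had none. Of the kept probes, 20764 had a symbol. The array annotation uses the mouse assembly mm9, so no coordinates are given and positions served only for distance from Ndrg2 and gene order. Each gene was represented by its probe with the highest mean intensity, which left 15759 genes. Among 675 called genes with another tested probe and not within 40 Mb of Ndrg2, the brightest other probe had the same sign in 70.2%.

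An intercept-only linear model was fitted to the log2 ratios of the 4 arrays with limma's lmFit and eBayes (residual degrees of freedom 3, prior degrees of freedom 4.47). The p-values were adjusted by Benjamini-Hochberg over all kept probes, and a gene was called at an adjusted p under 0.05. The within-array ratio already pairs the samples of 1 replicate number, so the replicate block is part of the design. Without a test, genes were counted that passed 1.5 fold in the same direction on all 4 arrays, after the series' design text. For Ndrg2 an exact two-sided sign-flip test was added. The share of called genes within 10 Mb of Ndrg2 was compared with all other genes by Fisher's exact test, with Ndrg2 itself left out of both groups. Intervals are at 95%.

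A set of 36 gene lists was tested by camera against all other genes, with a preset correlation of 0.01, with an estimated correlation, and by fry, each adjusted by Benjamini-Hochberg over the lists. They covered the NDRG family; astrocytes, reactive astrocytes, microglia, oligodendrocytes and their precursors, neurons in general, excitatory and inhibitory neurons, endothelium, mural and meningeal cells and choroid plexus; striatum, hippocampus, thalamus and blood; immediate early, circadian, glucocorticoid, interferon, inflammatory, PI3K-AKT, FoxO, Wnt, hypoxia, stress and cell cycle genes; glutamate uptake, glutamate receptors, GABA genes, glial potassium and water homeostasis, glycolysis, oxidative phosphorylation and cholesterol synthesis; and genes that differ between C57BL substrains or are sex-linked. The lists, the tests, the thresholds and the alternatives were chosen before the data were examined, apart from the additions named in the closing section.

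The rule for naming genes was fixed in the same way. It names Ndrg2 and its family, the 10 called genes with the largest log2 ratio in each direction that had 1 sign on all 4 arrays and an established symbol, up to 4 called members of each list by size (or up to 2 of any size where none was called), and up to 8 called genes within 5 Mb of Ndrg2.

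The pipeline was tested on simulated arrays with known changes in 200 of the 15759 genes. It recovered 43 of 61 genes changed by 1.2 fold (70.5%), all 79 changed by 1.5 fold and all 60 changed by 2 fold. Of 197 calls, 15 were false (7.61%). The 1 simulated list was called and no other list. The simulated region around Ndrg2, where no excess of changes was planted, gave an odds ratio of 0.459 (95% interval 0.0115 to 2.62). The simulated noise was independent between spots and arrays. It held no dye bias of a probe shared by the arrays and no correlation between genes. The share of false calls and the list result therefore do not carry over to data with either.

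The alternatives tried were no background correction, an offset of 16, the processed signals, the deposited table, median centring without loess, scaling between arrays, no filter on dim probes, a filter on both channels, saturated spots left out, each replicate left out, eBayes with an intensity trend, array weights, and separate channels without the replicate block. Other thresholds were an adjusted p of 0.10, limma's treat against 1.2 fold, 1.5 fold by the mean, 2 fold, and windows of 5 and 20 Mb. For the lists, the mean of all probes of a gene and the estimated correlation were used. Intensities were not compared with other arrays, and probes without a symbol entered the adjustment but no count of genes.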

Results

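Gene expression in the cerebral cortex was compared between adult male mice labelled as Ndrg2 knockouts and wild-type males, on the C57BL/6N background. Ndrg2 belongs to the N-myc downstream regulated family and is expressed mostly by astrocytes in the brain. The animals were 3 months old. There were 4 dual-colour Agilent mouse arrays, and each carried 1 RNA sample labelled knockout, dyed with Cy5 (red), against 1 sample labelled wild type, dyed with Cy3 (green). Every ratio is the log2 of knockout over wild type as labelled, with the SD over the arrays after ± and n = 4. No pair of samples exchanged dyes, so any dye difference specific to a probe adds to the genotype difference on each array. The labels do not say whether a sample was 1 mouse or a pool, or whether all samples came from separate animals, so the p-values measure the spread between these samples. The median spot signal ran from 94 to 122 in green and from 283 to 336 in red, over local backgrounds of 22 to 26 and 87 to 96. Between 71.2% and 74.0% of probes were well above background in a channel, and the number of arrays limits the precision.

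Log2 ratios correlated between arrays across probes, which are not independent replicates. Pearson's r was 0.688 for arrays 1 and 2 and 0.547 for arrays 3 and 4. The other pairs lay between 0.356 and 0.461. The median over all pairs was 0.455. Dye effects shared by all arrays also raise these correlations, so they do not by themselves show agreement on genotype.

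The first question was whether the targeted gene itself was lower in the samples labelled knockout. It was not. The only Ndrg2 probe tested (NM_013864) gave log2 ratios of 0.11, 0.37, 0.40 and 0.38 on arrays 1 to 4, all higher in the samples labelled knockout. The mean was 0.32 ± 0.14, with an adjusted p of 0.0173 from limma. An exact two-sided sign-flip test over the arrays gave p = 0.125, the smallest value that 4 arrays allow. Ndrg2 signal was strong in both channels, and only 2.34% of tested genes were brighter. The Ndrg2 call was lost without replicate 2 (0.30, adjusted p 0.0796) and without replicate 3 (0.29, adjusted p 0.0651), and with the scanner software's processed signals (0.26, adjusted p 0.0663). The labels do not say which part of Ndrg2 was deleted, and a probe outside that part checks nothing, so the direction of every ratio rests on the labels alone.

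Among the relatives of Ndrg2, the neuronal gene Ndrg4 had a log2 ratio of 0.22 ± 0.15 and missed the threshold (adjusted p 0.0520), which it passed without replicate 4 (0.27, adjusted p 0.0492). Ndrg4 was among the brightest genes. Ndrg3 was at -0.03 ± 0.06 (adjusted p 0.639) and the hypoxia-induced gene Ndrg1 at -0.02 ± 0.14 (adjusted p 0.810). Ndrg3 and Ndrg1 took the opposite sign under median centring without loess (0.48 and 0.37), which shifted the median of all genes to 0.28, and Ndrg1 also without replicate 3 (0.04). Of the 4 family genes, 1 passed over all genes and 2 when adjusted over the list alone.

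The second question was which genes differed between the samples labelled knockout and wild type. Most differences were small, and the largest lay on chromosome 14, which carries Ndrg2. Of 15759 genes tested, 2354 passed adjusted p 0.05 in limma, 1434 higher and 920 lower in the samples labelled knockout. The median size of their log2 ratio was 0.23, and 98.4% were under 1.5 fold. The series' own criterion, 1.5 fold, was met on all 4 arrays by 15 genes, 7 higher and 8 lower. Of those genes, 10 lay on chromosome 14, which held 3.45% of the genes tested. By the mean alone, 43 genes passed 1.5 fold, 15 of them on chromosome 14, and with the processed signals 47 passed on all 4 arrays, 18 of them on chromosome 14, so most then lay elsewhere.

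The count of genes depended on each array. It was 640 without replicate 1, 452 without replicate 2, 804 without replicate 3 and 1544 without replicate 4. Of the 125 named genes tested without each array, 65 lost the call without replicate 1, 78 without replicate 2, 62 without replicate 3 and 36 without replicate 4. The scanner software's processed signals gave 1329 genes. Brightness mattered as well, because 87 of the 158 brightest genes passed, 83 of them higher and 4 lower.

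The largest changes were in neighbours of Ndrg2. Samd4, which encodes the RNA-binding translational repressor Smaug1, had a log2 ratio of -2.78 ± 0.12 (adjusted p 1.0e-06). Rnase4, which encodes a secreted ribonuclease, was at 2.29 ± 0.04 (adjusted p 8.5e-07). Myh7, the slow myosin heavy chain of heart and muscle, was at -1.31 ± 0.16 (adjusted p 0.00023), and the neutral amino acid transporter gene Slc7a8 at -1.12 ± 0.14 (adjusted p 0.000295). The noncoding antisense gene Zfhx2os was at -0.87 ± 0.13, and Supt16, a subunit of the histone chaperone FACT, at 0.72 ± 0.11. In the order of tested genes counted from Ndrg2, these lay between positions -38 (Samd4) and 39 (Zfhx2os). The angiogenin genes Ang (-0.60 ± 0.07, adjusted p 0.000754) and Ang4 (-0.60 ± 0.13, adjusted p 0.00142) lay closer, at positions -10 and -4. Each of these genes passed with each replicate left out in turn. None of them had another tested probe, so no other probe could check these values.

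Another group of large changes lay farther along chromosome 14, at positions 183 to 230. The synaptic secreted protein gene Lgi3 was at 0.95 ± 0.13 (adjusted p 0.000515). The actin-bundling gene Dmtn was at -0.97 ± 0.02 (adjusted p 7.4e-05). The esterase gene Esd was at -0.77 ± 0.06 (adjusted p 0.000295), with its other probe at -0.32, and the cell cycle regulator gene Rgcc was at 0.75 ± 0.09 (adjusted p 0.000709). Lgi3, Dmtn and Rgcc had no other tested probe. No gene more than 40 Mb from Ndrg2 on chromosome 14 met the 1.5-fold criterion among 83 tested.

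Smaller changes were dense in the same region. Within 10 Mb of Ndrg2, 56 of 172 tested genes passed (32.6%), 31 higher and 25 lower, against 14.7% of all other genes. The odds ratio was 2.79 (95% interval 1.99 to 3.89, two-sided Fisher's exact p 4.7e-09). Here and below, Fisher's test takes genes as independent units, so its p-values and intervals do not measure the spread between samples. Without replicate 1 the odds ratio was 5.19 and without replicate 2 it was 4.61. Under median centring it was 1.21 and no longer passed (two-sided Fisher's exact p 0.422). That setting called 10645 genes higher and 2326 lower of 15759. With most genes called everywhere, its odds ratio cannot show whether the cluster was lost. For the 1.5-fold criterion it was 62.4 (95% interval 18.1 to 198), from 6 of 172 genes, Samd4, Rnase4, Supt16, Slc7a8, Myh7 and Zfhx2os, against 9 elsewhere.

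**Figure D1:**
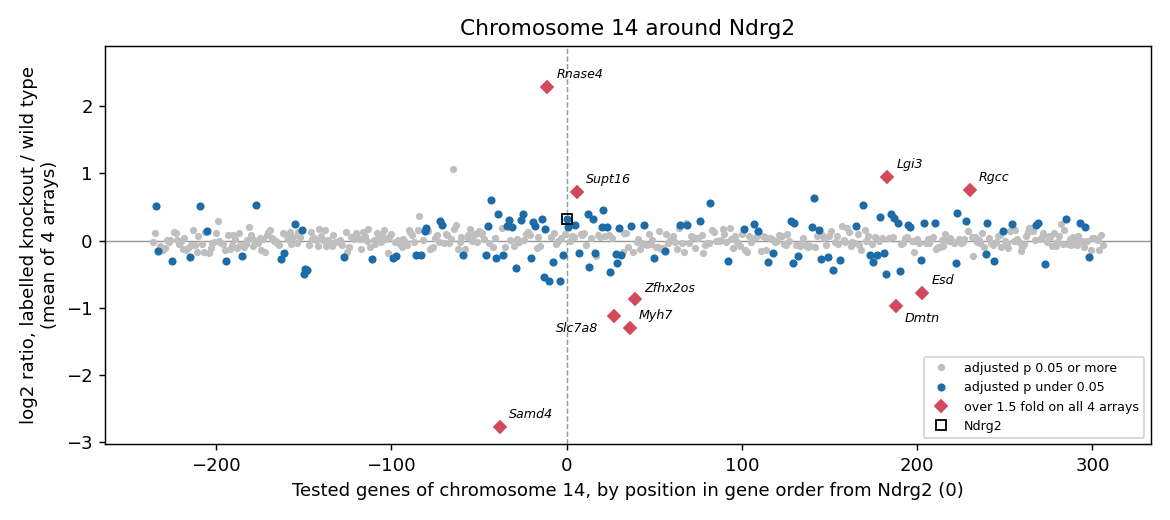
Mean log2 ratio over 4 arrays (y axis, samples labelled knockout over wild type) of each tested gene of chromosome 14, placed by its position in gene order from Ndrg2 (x axis). Red diamonds are the 10 genes over 1.5 fold on all 4 arrays, from Samd4 (-2.78) to Rnase4 (2.29), blue points other genes past adjusted p 0.05, and the open square is Ndrg2 (0.32).

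Away from chromosome 14, 5 genes met the 1.5-fold criterion on all arrays. The myelin basic protein gene Mbp was at 0.77 ± 0.11 (adjusted p 0.000754), but the median of its 2 other probes was 0.18. The bile acid transporter gene Slc10a1 was at 0.76 ± 0.03 and Kctd14 at 0.70 ± 0.06; both were among the brightest genes, and the 2 other probes of Kctd14 had a median of 0.16. The ubiquitin ligase gene Hecw2 was at -0.69 ± 0.10, with 2 other probes at a median of -0.25, and Tmem74b was at -0.69 ± 0.11, with its other probe at -0.47. The remaining genes with the largest changes were Per2 (0.77 ± 0.31, adjusted p 0.00753), Egr1 (0.70 ± 0.39, adjusted p 0.0188), the glutaredoxin gene Glrx2 (0.68 ± 0.09), the splicing regulator gene Celf3 (-0.67 ± 0.36) and the kinase gene Hunk (-0.65 ± 0.21, adjusted p 0.00425). Glrx2 was also among the brightest genes and its 2 other probes had a median of 0.01, while the other probe of Hunk was at -0.65. Celf3 lost its call without replicate 2 (adjusted p 0.0684), and Egr1 without replicate 1 (0.55) and without replicate 2 (0.64, adjusted p 0.0855).

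The third question was whether genes of known cell types and pathways moved together. Of 36 lists fixed in advance, 9 passed adjusted p 0.05 in camera with its preset correlation, 7 higher and 2 lower in the samples labelled knockout. None of the 9 held with an estimated correlation, under which 1 list reached an unadjusted p under 0.05. The fry test, which asks whether a list's genes move on balance 1 way and compares them with no other genes, passed 11 lists, 5 of them among these 9. It did not pass the mural and meningeal list (adjusted p 0.0560), the reactive astrocyte list (0.0606), the GABA list (0.0703) or the immediate early list (0.329). Median centring without loess, which shifted the median of all genes to 0.28, put both lower lists above 0 yet under that median, at 0.17 for cholesterol synthesis and 0.27 for GABA genes. It ended both of these calls (adjusted p 0.828 and 0.395) and 5 of the other 7.

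Genes of the meninges, the connective tissue that covers the cortex, were higher in the samples labelled knockout. The list of mural and meningeal fibroblast markers had a median log2 ratio of 0.42, with array medians of 0.33, 0.30, 0.14 and 0.62 (camera adjusted p 2.1e-06, and adjusted p = 0.508 with an estimated correlation). Of its 22 genes, 12 rose, 10 did not pass and none fell; 15 rose when adjusted over the list alone. The proteoglycan gene Lum was at 0.59 ± 0.11 (adjusted p 0.00112) and passed with each replicate left out in turn. The collagen gene Col1a1 was at 0.52 ± 0.29, the proteoglycan gene Dcn at 0.50 ± 0.26 and the matrix gene Mgp at 0.52 ± 0.41 (adjusted p 0.0446). Mgp fell to 0.32 without replicate 4, though it still passed (adjusted p 0.0191), and it missed the threshold without replicates 1, 2 or 3 in turn (adjusted p 0.0728, 0.0969 and 0.0929). Dcn missed it without replicate 1 (adjusted p 0.0626) and without replicate 2 (adjusted p 0.0655), and Col1a1 without replicates 1, 2 or 4 in turn (adjusted p 0.0665, 0.0839 and 0.0571).

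All 12 genes that rose were among the 13 meningeal genes, whose median was 0.48. Of the 9 mural genes, those of pericytes and vascular smooth muscle, none passed in limma and 3 had an unadjusted p under 0.05; their median was 0.12. The smooth muscle actin gene Acta2, chosen after its values were seen, was at 0.53 ± 0.66, with array 4 alone at 1.51.

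**Figure D2:**
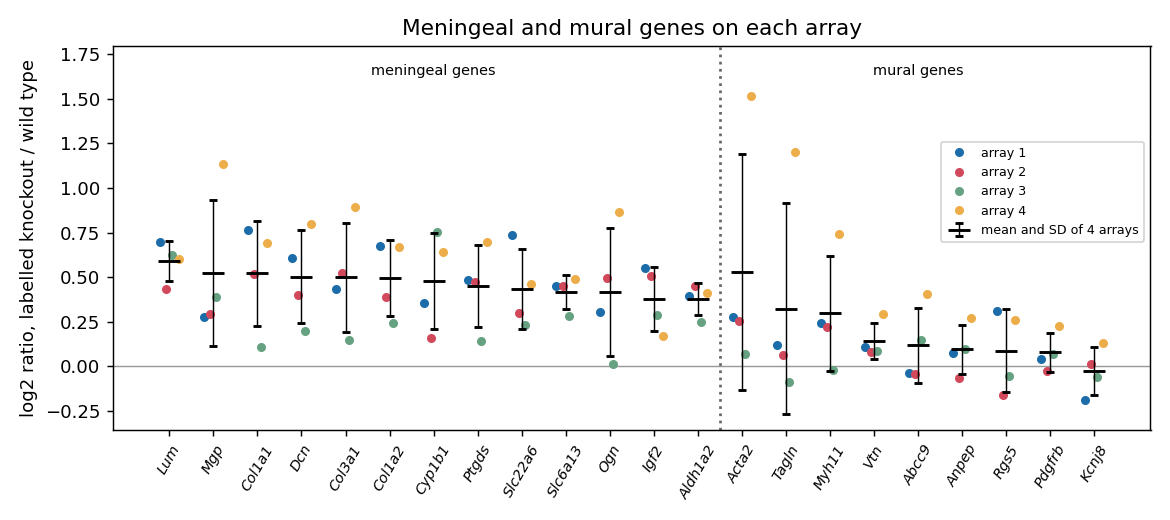
Log2 ratio (y axis, samples labelled knockout over wild type) of each meningeal and mural gene (x axis), with points for the 4 arrays and bars for the mean and SD. The median was 0.48 over the 13 meningeal genes and 0.12 over the 9 mural genes.

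Genes of cholesterol synthesis were lower in the samples labelled knockout, with a median log2 ratio of -0.19 and array medians of -0.11, -0.19, -0.23 and -0.23; under median centring it was 0.17, above 0 but under the shifted median of all genes (0.28). Camera gave an adjusted p of 4.1e-06, and adjusted p = 0.508 with an estimated correlation. Of 18 genes, 9 fell, 9 did not pass and none rose; 12 fell when adjusted over the list alone. Among those that fell, the sterol enzyme gene Msmo1 was at -0.27 ± 0.09 (adjusted p 0.0152), squalene epoxidase (Sqle) at -0.26 ± 0.10 and farnesyl diphosphate synthase (Fdps) at -0.24 ± 0.05. These 3 lost the call without replicate 2 (adjusted p 0.0662, 0.0800 and 0.0724) and without replicate 3 (adjusted p 0.0621, 0.0696 and 0.0572).

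Astrocyte genes were slightly higher in the samples labelled knockout. Of 23 astrocyte markers, 4 rose, 19 did not pass and none fell; 8 rose when adjusted over the list alone. The list median was 0.13 (camera adjusted p 0.0284, and adjusted p = 0.508 with an estimated correlation). The glycolytic enzyme gene Aldoc was at 0.24 ± 0.02 (adjusted p 0.0113), the sodium pump subunit gene Atp1b2 at 0.19 ± 0.03 and the glutamine synthetase gene Glul at 0.18 ± 0.05. Aldoc lost the call without replicate 2 (adjusted p 0.0572) or replicate 3 (adjusted p 0.0520), Glul without replicates 1, 2 or 3 (adjusted p 0.0889 to 0.111), and Atp1b2 with any 1 replicate left out (adjusted p 0.0527 to 0.0853). Aldoc was among the brightest genes, most of which lay higher.

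Among 29 genes induced in reactive astrocytes, 9 rose and 20 did not pass; adjusted over the list alone, 13 rose and 1 fell. Their median was 0.14 (camera adjusted p 0.00885, and adjusted p = 0.508 with an estimated correlation). The matrix gene Fbln5 was at 0.50 ± 0.18 (adjusted p 0.00751) and passed with each replicate left out in turn. The small heat shock gene Hspb1 was at 0.64 ± 0.35, the membrane protein gene Emp1 at 0.62 ± 0.35 and the intermediate filament gene Vim at 0.43 ± 0.28. Across arrays 1 to 4, Emp1 (0.70, 0.51, 0.21 and 1.04) and Vim (0.43, 0.28, 0.20 and 0.82) varied like the meningeal gene Dcn (0.61, 0.40, 0.20 and 0.80); this likeness was seen in the values and not tested. Hspb1, Emp1 and Vim lost the call without replicate 2 (adjusted p 0.0740, 0.0721 and 0.0788), and Emp1 and Vim also without replicate 1 (adjusted p 0.0668 and 0.0825).

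Genes that import, export and convert glutamate were higher as a list of 18, with a median of 0.13 (camera adjusted p 0.0381, and adjusted p = 0.508 with an estimated correlation). Of these, 5 rose, 13 did not pass and none fell; adjusted over the list alone, 10 rose and 2 fell. The neutral amino acid transporter gene Slc1a4 was at 0.53 ± 0.10 (adjusted p 0.00127) and the cystine/glutamate exchanger gene Slc7a11 at 0.50 ± 0.06 (adjusted p 0.000878), and both passed with each replicate left out in turn. The vesicular transporter gene Slc17a6 was at 0.45 ± 0.34 (adjusted p 0.0408) and lost the call with any 1 replicate left out (adjusted p 0.0521 to 0.0773), with its lowest value, 0.29, without replicate 2. The list's own call ended without replicate 1 (adjusted p 0.0822) and without replicate 2 (adjusted p 0.0580).

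GABA receptor and transporter genes were lower, with a median of -0.10 over 17 genes (camera adjusted p 0.0381, and adjusted p = 0.508 with an estimated correlation). Under median centring the list stood at 0.27, above 0 but just under the shifted median of all genes (0.28). Of these, 3 fell, 14 did not pass and none rose; 5 fell when adjusted over the list alone. Among them were the receptor subunit genes Gabra4 (-0.29 ± 0.08, adjusted p 0.0108) and Gabrd (-0.27 ± 0.14, adjusted p 0.0277). Gabra4 passed with each replicate left out in turn. Gabrd missed the threshold without replicates 1, 3 or 4 (adjusted p 0.0631 to 0.0879). The list missed the threshold without replicate 1 (-0.07, adjusted p 0.0973), and its median shrank to -0.05 without replicate 2, though it passed (adjusted p 0.0317).

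Immediate early genes, which neurons induce within minutes of activity, varied most between arrays. Their median was 0.24 over 24 genes (camera adjusted p 0.0284, and adjusted p = 0.734 with an estimated correlation), but the array medians were 0.60, 0.36, -0.19 and 0.11. Egr1, Ier5 (0.39 ± 0.29, adjusted p 0.0420) and the scaffold gene Homer1 (0.20 ± 0.05, adjusted p 0.0204) rose, and 21 genes did not pass; adjusted over the list alone, 6 rose and 1 fell. Ier5 and Homer1 lost the call without replicates 1, 2 or 3 (adjusted p 0.0565 to 0.155 and 0.0584 to 0.0878). The list's call ended without replicate 1 (0.14, adjusted p 0.198) and without replicate 2 (0.22, adjusted p 0.0719), and with array weights (adjusted p 0.0605).

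Circadian genes had a median of 0.12 (camera adjusted p 0.0381, and adjusted p = 0.508 with an estimated correlation). Of 18 genes, Per2 and the transcription factor gene Hlf (0.18 ± 0.06, adjusted p 0.0345) rose, 16 did not pass and none fell; 3 rose when adjusted over the list alone. Hlf lost its call with any 1 replicate left out (adjusted p 0.0652 to 0.118). The list's call ended without replicate 2 (adjusted p 0.0580) and without chromosome 14 (adjusted p 0.0531). Of 20 excitatory cortical neuron markers, 3 rose, 1 fell and 16 did not pass, with a median of 0.11 (camera adjusted p 0.0381, and adjusted p = 0.508 with an estimated correlation). Adjusted over the list alone, 8 rose and 1 fell. The transcription factor gene Neurod6 rose, at 0.29 ± 0.04 (adjusted p 0.00686), and Emx1 fell, at -0.31 ± 0.16 (adjusted p 0.0224), though not without replicates 1, 2 or 4 (adjusted p 0.0575 to 0.0763). The excitatory list lost its call without replicate 2 (adjusted p 0.0560) and without replicate 4 (adjusted p 0.0501). It also did so with the mean of all probes of a gene (0.08, adjusted p 0.139), with separate channels (adjusted p 0.110) and without chromosome 14 (adjusted p 0.0644).

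**Figure D3:**
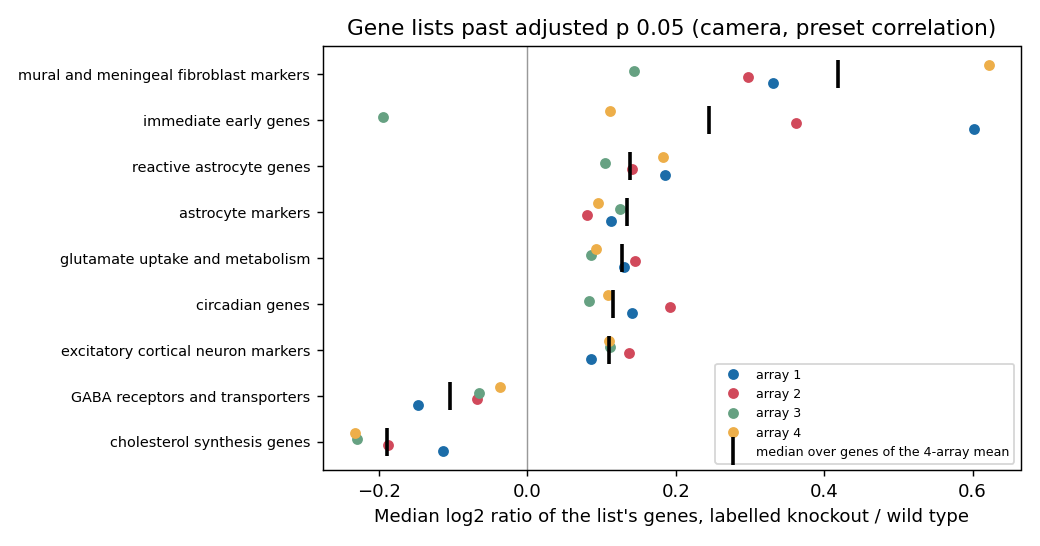
Median log2 ratio (x axis, samples labelled knockout over wild type) of the genes of each of the 9 lists (y axis) past adjusted p 0.05 in camera, with points for the 4 arrays and a bar for the median of the 4-array means. Array medians run from -0.19 to 0.60 for immediate early genes, and both lists left of 0, cholesterol synthesis and GABA genes, move to 0.17 and 0.27 under median centring without loess, where the median of all genes is 0.28.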

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

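The tests chosen only after the result was seen were those of the spike-in probes, of dye bias, strain variants and a retained stretch on chromosome 14, and of a lower share of neurons.

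For 12 of 162 values examined, the value on 1 array stood so far from the other 3 that its gap to the nearest, over the whole range, passed Dixon's 95% critical value. By the construction of that value, chance alone does so in about 1 in 20. There were 2 such values on array 1, 4 on array 2, 2 on array 3 and 4 on array 4. Ndrg2 was at 0.11 on array 1, against 0.37 to 0.40 on the other arrays, and Hunk at -0.96 on array 1, against -0.55 to -0.53. On array 2, Lef1 was at 0.22 (others 0.36 to 0.37), Gapdh at 0.43 (others 0.36 to 0.37), Atp5c1 at -0.086 (others -0.19 to -0.18), and the median of the general neuronal genes at 0.16 (others 0.02 to 0.03). On array 3, Isg15 was at -0.62 (others -0.05 to 0.03) and the median of the oligodendrocyte and myelin genes at -0.22 (others 0.04 to 0.08). On array 4, Mgp was at 1.13 (others 0.28 to 0.39), Ccna2 at 0.45 (others 0.18 to 0.21), Atp1b2 at 0.24 (others 0.17 to 0.18) and Dag1 at -0.27 (others -0.15 to -0.13).

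For the first pattern, the large number of small changes, 1 of 8 sign patterns of the arrays, the real one, gave as many genes (2354, and 0 in the highest of the others), which are too few patterns for a share under 0.05. With the channels as separate samples, only 1 of 35 splits gave as many genes, the real one (664), so chance can be excluded only if channels may be exchanged across arrays; the highest other, with 148, set arrays 1 and 2 against arrays 3 and 4. That exchange ignores the pairing within arrays, and the 8 splits that part every pair (highest other 1 gene) are too few for a share under 0.05. Dye bias specific to a probe stays open, because the brightest other probe of a called gene shared its sign in 70.2% of 675 genes not within 40 Mb of Ndrg2 (95% interval 66.6% to 73.7%), and in 60.2% of uncalled genes, but also passed with that sign in only 14.2%, with a median of 0.06 in that direction against 0.23; the share that a change of the whole gene would give was not measured. The 10 spike-in probes left the line fitted to their known ratios by an SD of 0.25 that the arrays shared, about the median change of the called genes (0.23). That SD comes from the processed signals, whereas the calls rest on loess ratios. Over all kept probes, the SD of the loess log2 ratio on an array was only 0.15 to 0.20. Gene probes as a whole thus deviated less than the spike-ins, whose spread cannot tell how many calls come from such deviations. Knockout biology cannot be separated from dye without exchanged dyes.

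The second pattern is the cluster of changed genes around Ndrg2. Other probes cannot decide on dye bias here. The brightest other probe of a called gene within 10 Mb shared its sign in 8 of 14 genes (57.1%, 95% interval 28.9% to 82.3%). Nor can the odds ratio of 1.21 under median centring, where most genes passed throughout. A bias that belongs to single probes does not depend on gene position. The excess within 10 Mb (32.6% against 14.7% of other genes, 95% interval of the odds ratio 1.99 to 3.89) argues against it as the source of the whole cluster. For single genes dye bias stays open. As the source of every call within 10 Mb, strain variants that weaken binding of the samples labelled knockout would lower nearly all called genes there. Of these, 44.6% were lower (95% interval 31.3% to 58.5%), and 31 of 56 would be with the labels turned. Such variants are thus not the source of all these calls. That share pools genes that pass at the rate seen elsewhere (14.7%), so it does not decide on single large changes. How much of the excess over that rate such variants could make was not measured. Of the 6 genes over 1.5 fold within 10 Mb, 4 were lower and 2 higher. A stretch of chromosome 14 from another strain, kept from the stem cells in which the gene was targeted, is a candidate explanation: beyond 40 Mb the odds ratio against other chromosomes was 1.09 (95% interval 0.550 to 1.98; Fisher's exact p 0.756), from 13 of 83 genes. The labels name neither the stem cells nor the number of backcrosses, and an effect of the targeted gene on its neighbours was not tested.

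The third pattern is the rise of meningeal genes: a lower share of neurons would raise all other cell types alike, but the endothelial median was 0.03 (95% interval to 0.18) and the microglial median 0.046 (to 0.13), both under 0.21, the least set for that explanation. More meninges in the samples labelled knockout may account for it, since the meningeal genes lay 0.36 above the mural genes of the same list (95% interval 0.14 to 0.42), and the labels name no step that removes meninges. The intervals in this paragraph come from resampling the genes of a list, not the arrays, so they do not measure the spread between samples. On arrays 1 to 4 the meningeal medians were 0.49, 0.45, 0.25 and 0.67, and the mural medians 0.11, 0.01, 0.07 and 0.29. No gene of the list is in another list, though cortical glia also express Ptgds (0.45), and whether the rise of Emp1 and Vim among the reactive astrocyte genes shares this source was not tested. Dye bias cannot be told apart here, because there were 0 other probes of the list's genes. A change in the meninges of the knockout itself was not tested and stays open.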

How the results depend on the processing

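The main results were compared with their value under another setting 162 times. Of these comparisons, 115 held, 6 fell short of the threshold, 41 counts or values moved and none reversed. A result with a direction and a threshold held if it kept both direction and side of the threshold. Most main results are counts or the correlation between arrays, which have neither, and these held within a set margin of their main value. The count of higher genes, 1434, was rated as held at 956 without replicate 4. It was rated as moved at 779 with the processed signals. Of 180 such comparisons of lists, 151 held, 27 fell short and 2 reversed. Of 2125 of named genes, 1581 held, 501 fell short, 14 newly passed and 29 reversed. The cause was not tested, except where named. Outlier spots kept and chromosome 14 left out were added after the data were seen; without chromosome 14, 2183 genes passed and 7 of the 9 list calls held, while excitatory neurons (adjusted p 0.0644) and circadian genes (0.0531) fell short. All planned settings were run; leaving out saturated spots moved nothing, since there were none, and says nothing about stability.

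Each replicate left out gave 452 to 1544 genes, 321 to 956 higher and 131 to 588 lower, with fewer arrays as part of the cause. Without replicates 1 to 4 in turn, 619, 444, 754 and 1353 of these genes were among the 2354. Ndrg2 ran from 0.29 to 0.39 and Ndrg1 from -0.069 to 0.036. With the processed signals, and equally with the deposited table, 1329 genes passed (779 higher, 550 lower), of which 1121 were among the 2354; 47 genes, 18 on chromosome 14, were over 1.5 fold on all arrays, and Ndrg2 was at 0.26. Separate channels with no replicate block, where the pairing is lost, gave 664 genes (455 higher, 209 lower), 663 of them among the 2354, and Ndrg2, still at 0.32, missed the threshold (adjusted p 0.0621). The adjusted p of Ndrg2 ran up to 0.0796 over its settings.

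By construction, an adjusted p of 0.10 gave 4061 genes (2379 higher, 1682 lower) and treat against 1.2 fold 48 (38 higher, 10 lower). An offset of 16 gave 23 genes over 1.5 fold on all arrays, the mean alone 43, and 2 fold 3, all 3 on chromosome 14. The estimated correlation left 0 lists.

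Median centring without loess shifted the median of all genes to 0.28. Under it 12971 genes passed (10645 higher, 2326 lower, 82.1% higher against 60.9%), 359 were over 1.5 fold on all arrays (29 on chromosome 14), the median correlation between arrays was 0.837 and the odds ratio near Ndrg2 1.21. The share higher was also 79.2% with treat and 71.0% without replicate 2, and at the other end 53.6% with no background correction (1301 higher, 1126 lower). The cholesterol synthesis list reversed to 0.17 and the GABA list to 0.27, both still under the shifted median. Genes that reversed included Ndrg3 (0.48), Ndrg1 (0.37), Atp5c1 (0.37), Bnip3 (0.30), Ermn (0.29), Cox7c (0.27), Npy (0.22), Msmo1 (0.20), Gabrd (0.19), Dag1 (0.18), Fdps (0.17), Dlg4 (0.16), Isg15 (0.16), Penk (0.15), Wfs1 (0.14), Sqle (0.14), Gria1 (0.13), Eif2s3y (0.12), Grik1 (0.093), Ntng1 (0.080), Gabra4 (0.073), Bok (0.054), Dlx1 (0.032), Arrdc2 (0.026), Trpc6 (0.021), Ankrd37 (0.017) and Lyve1 (-0.062). After the shift was subtracted, 24 of all 30 lists and genes that reversed under it had their original sign, as had 127 of all 135.

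Fewer dim genes passed, for a cause that was not tested: 292 of the 3940 dimmest genes passed, against 717 of the 3782 brightest after the 158 brightest of all.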

Other observations

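The remaining lists did not pass in camera with its preset correlation, whose adjusted p is given here for each. The fry test passed 6 of them, all higher: choroid plexus markers (adjusted p 0.0137), FoxO targets (0.0211), PI3K-AKT genes (0.0225), glial potassium and water homeostasis (0.0241), thalamic markers (0.0411) and Wnt targets (0.0480). No test given with these lists was chosen after its result was seen. Of 19 microglial markers 4 rose and none fell (median log2 ratio 0.05, adjusted p 0.236; 6 rose adjusted over the list alone), among them Fcrls (0.24 ± 0.06) and the fractalkine receptor gene Cx3cr1 (0.19 ± 0.07). Of 19 oligodendrocyte and myelin genes Mbp rose and Ermn fell (-0.29 ± 0.07), though the other probe of Ermn was at 0.18, and the list median was 0.01 (adjusted p 0.654). No oligodendrocyte precursor marker of 14 passed in limma, where 3 had an unadjusted p under 0.05 (median 0.09, adjusted p 0.0953). Of 16 general neuronal genes 4 rose and 1 fell (median 0.05, adjusted p 0.525), and of 21 inhibitory interneuron markers 2 rose and 2 fell (median -0.01, adjusted p 0.616), with the peptide genes Cck at 0.27 ± 0.16 and Npy at -0.21 ± 0.10. Of 18 endothelial markers 4 rose (median 0.03, adjusted p 0.425), among them the glucose transporter gene Slc2a1 (0.50 ± 0.34), and of 9 choroid plexus markers 1 did (Kcnj13, 0.38 ± 0.22; median 0.10, adjusted p 0.242).

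No list of markers of neighbouring brain regions passed in camera. Of 14 striatal markers the phosphodiesterase gene Pde10a rose (0.54 ± 0.16, adjusted p 0.00380) and the enkephalin gene Penk fell (-0.26 ± 0.18), with an adjusted p of 0.654 for the list. Of 13 hippocampal markers 4 fell, Bok (-0.32 ± 0.09), Wfs1 (-0.27 ± 0.09), Trpc6 (-0.26 ± 0.15) and Lct (-0.25 ± 0.16), and none rose (median -0.05, adjusted p 0.0953). Of 14 thalamic markers 4 rose and 1 fell (median 0.09, adjusted p 0.236), among them Lef1 (0.33 ± 0.07, adjusted p 0.00613). Of 12 blood cell genes the neutrophil gene S100a9 fell (-0.56 ± 0.19, adjusted p 0.00543; list median -0.04, adjusted p 0.588).

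Signalling lists closest to the threshold were Wnt and beta-catenin targets (3 of 18 rose, 1 fell, median 0.12, adjusted p 0.0636), oxidative phosphorylation subunits (2 of 23 fell, Cox7c at -0.22 ± 0.07 and Atp5c1 at -0.16 ± 0.05, median -0.04, adjusted p 0.0856), FoxO targets (6 of 19 rose, 2 fell, median 0.16, adjusted p 0.0912) and inflammatory NF-kB genes (1 of 15 rose, median 0.10, adjusted p 0.0923). The repressor gene Bcl6, a FoxO target, was at 0.38 ± 0.12 (adjusted p 0.00826). Of 25 PI3K-AKT pathway genes 4 rose (median 0.03, adjusted p 0.335), among them the insulin receptor substrate gene Irs1 (0.41 ± 0.22), whose other probe was at -0.06. Of 19 glucocorticoid-responsive genes 4 rose and 1 fell (median 0.08, adjusted p 0.236), with the metallothionein gene Mt1 at 0.45 ± 0.12 (adjusted p 0.00399). No interferon-responsive gene of 24 passed in limma, where 1 had an unadjusted p under 0.05 (adjusted p 0.658). Stress and unfolded protein genes (8 of 21 rose, 1 fell, median 0.14, adjusted p 0.107), cell cycle genes (2 of 14 rose, median 0.06, adjusted p 0.345) and hypoxia-responsive genes (2 of 18 rose, 2 fell, median 0.06, adjusted p 0.656) did not pass as lists.

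Of 24 glutamate receptor genes 1 rose and 3 fell (median -0.06, adjusted p 0.135), with the kainate receptor gene Grik3 at 0.30 ± 0.15 and the AMPA receptor gene Gria1 at -0.24 ± 0.16. Of 16 genes of glial potassium and water homeostasis 3 rose and 1 fell (median 0.08, adjusted p 0.101). Of 22 glycolysis and lactate shuttle genes 5 rose and 2 fell (median 0.08, adjusted p 0.0953); the lactate transporter gene Slc16a7 was at -0.39 ± 0.08 (adjusted p 0.00387), and Gapdh at 0.38 ± 0.04, though its 6 other probes had a median of 0.04. Of 4 genes that differ between C57BL substrains Entpd4, itself on chromosome 14, rose (0.21 ± 0.04; list adjusted p 0.588). None of 4 sex-linked genes passed in limma, where 1 had an unadjusted p under 0.05 (median -0.08, adjusted p 0.269). The sign of the camera statistic was negative while the median and mean were positive for the oligodendrocyte list (median 0.01) and the striatal list, and the interferon list had a positive median (0.01) with a negative mean.

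Cck, Mt1 and Gapdh were among the 158 brightest genes, of which 83 rose and 4 fell. Of the genes named here, Mbp, Pde10a, Lef1, S100a9, Bcl6, Mt1, Slc16a7 and Gapdh passed with each replicate left out in turn. Each of the other genes said to differ lost its call without at least 1 replicate, with an adjusted p of up to 0.154 (Gria1 without replicate 2); Pnp2 was not examined in this way.

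The gene Pnp2, chosen after its values were seen, was above background in the samples labelled wild type on all 4 arrays and in none of those labelled knockout. Its measured signal was 1.46-fold lower in the samples labelled knockout (limma adjusted p 0.00155), and it lies at position -13 from Ndrg2. Both channels were dim, with mean log2 signals of 6.29 in the samples labelled knockout and 6.84 in those labelled wild type.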
